A study of Mus musculus with 20 samples.

How the data were processed

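RNA was measured in 20 libraries of mouse duodenal epithelium collected by laser-capture microdissection, in which a pulsed laser isolates small areas of a tissue section. Per the labels' protocols, the tissue came from 8-week-old male C57BL/6 mice, was frozen without fixation, sectioned at 8 µm and stained, and 15000 µm² of apical or of basal cell areas was pooled per library. The labels describe the areas by cell side and name no marker gene used to choose them. Poly(A) RNA was amplified with SMART-Seq v4 in 15 PCR cycles. Mice had fasted for 5 h, or had fasted for 5 h and then had food for 2 h, under a reversed light cycle. Each of the 4 groups (fasted apical, fasted basal, refed apical, refed basal) holds 5 libraries, grouped by their labels. The labels do not tie libraries to animals. Libraries were therefore treated as replicates, and if libraries of the same group share an animal the p-values are too small.

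Reads were converted with bcl2fastq 1.8.4 and quantified with kallisto 0.42.4 against GRCm38 transcripts, per the submitters' processing notes. The deposited tables give, per the file headers, an estimated count for each of 96626 transcripts, made by kallisto by sharing reads among the transcripts they match. They also give a deposited TPM value per transcript, scaled for effective length to a fixed total per library, which was used only in alternatives. Transcripts were assigned to GENCODE M21 genes by their stable identifiers. Of them, 95301 matched, 88747 of these in the same version, and 1325 did not. The unmatched transcripts stayed in the total counts per library and were left out of the tests of genes and gene lists. Estimated counts were summed per gene (32035 genes, of them 21743 protein-coding and 9653 pseudogenes) and rounded to whole numbers. Coordinates are GRCm38 positions from that annotation.

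Total counts per library ranged from 663493 to 5172246. These totals include transcripts that hold a run of at least 20 A or 20 T bases, to which 42.8 to 87.8% of a library's counts were assigned. Such transcripts make up 1.49% of the 96626. Outside them 242141 to 2808070 counts on matched transcripts remained per library. Reads carry no molecular identifiers, so counts are not numbers of molecules.

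Genes were tested with edgeR 4.0.16 (R 4.3.3), with quasi-likelihood tests, TMM normalization and filterByExpr by group (minimum count 10, minimum total 15), which kept 9742 genes. All 20 libraries entered 1 model of group means, with a common biological coefficient of variation of 0.697. Fold changes kept the default prior count of edgeR, and a prior count of 2 was used only for log2 CPM values. The comparisons were apical against basal in fasted mice, the same in refed mice, the mean of both, the difference between both (the change of polarity on refeeding), and refed against fasted on each side. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Fold changes are log2 values with standard errors (SE). CPM values are counts scaled to the TMM library size and given as mean ± SD over 5 libraries.

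Gene lists of 37 cell functions and cell types were written before the data were examined, and 32 with at least 4 measured genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. The level of the ribosomal protein list in a library is its mean log2 CPM, compared between groups with an exact two-sided permutation test over 252 splits. Shares of counts were compared in the same way, as a family of 56 tests.

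Genes were named by a rule fixed before the data were examined. In each comparison it takes the 10 largest changes in each direction among genes past the threshold with a mean of at least 20 CPM, leaving out clone names and ribosomal protein pseudogenes. For each list it takes up to 4 members with the smallest p. Where fewer than 5 genes pass, it takes the 5 with the smallest p. Apob, Apoa4, Vil1, Pigr, Malat1, Rpl4, Rplp0, Eef1a1 and mt-Co1 are always named for polarity. Malat1 was not among the genes measured. Estimated counts of near-identical genes can be split between copies, so Clca4b, H2-Q7, Igha, Igkc and ribosomal protein genes with processed copies are uncertain.

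Alternatives planned before the data were examined were DESeq2 size factors, no filter, a filter of at least 10 CPM in 5 libraries, DESeq2 1.42.0, limma voom with sample weights, limma on log2(TPM + 1), a gene length offset, the 10 libraries compared alone, a replicate block, and each library left out in turn. Added after the data were seen were versions without long-run or A/T-rich transcripts (a run, or at least 27 A or T in 30 bases), without certain libraries, without marker genes of other cell types, and with TPM rescaled without long-run transcripts. The closing section gives their effect.

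The tests were run on simulated counts for 9742 genes with 200 changed genes. The changed genes were drawn from those with a mean of at least 20 CPM, so recovery of less abundant genes was not measured. Each gene was simulated independently, without variation shared between genes of a library. For fasted apical against basal, edgeR recovered 11.9% of 2-fold, 74.6% of 4-fold and 93.9% of 8-fold changes with 2 false calls. For the change of polarity on refeeding it recovered 4.5, 23.9 and 78.8% with 5 false calls. For refed against fasted apical it recovered 3.0, 62.7 and 95.5% with 6 false calls, and for refed against fasted basal 4.5, 77.6 and 95.5% with 9. DESeq2 made 23 false calls for fasted apical against basal and 28 for refed against fasted apical. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Translation was not analysed here. Some genes that the naming rule selects are not reported here.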

Results

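RNA abundance was measured in apical and basal fragments of duodenal epithelium from fasted and refed mice, with 5 libraries in each of 4 groups. Total estimated counts averaged 3068342 ± 423616 (SD, n = 5) in fasted apical libraries (2379690 to 3391273) and 2455961 ± 717869 in fasted basal libraries (1466382 to 3172558). They averaged 3687334 ± 1611948 in refed apical libraries (985905 to 5172246) and 1913187 ± 1321394 in refed basal libraries (663493 to 3794027). Counts were found for 9476 to 14666 genes per library. Much of each total lay on transcripts with a run of at least 20 A or T bases, with 71.8 ± 12.7%, 67.5 ± 9.9%, 51.5 ± 14.3% and 56.6 ± 4.2% of counts in those groups. A single transcript of Dock10 (1, 80501073 to 80758527), with a run of 32 A bases, took 34.7% of counts on average. Outside such transcripts 242141 to 2808070 counts remained per library, under 400000 in fasted apical library 1 (285749), fasted basal library 1 (368853) and refed basal library 3 (242141). Spearman correlations between libraries of a group ranged from 0.538 to 0.904. All p-values measure only the spread between these libraries.

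**Figure D1:**
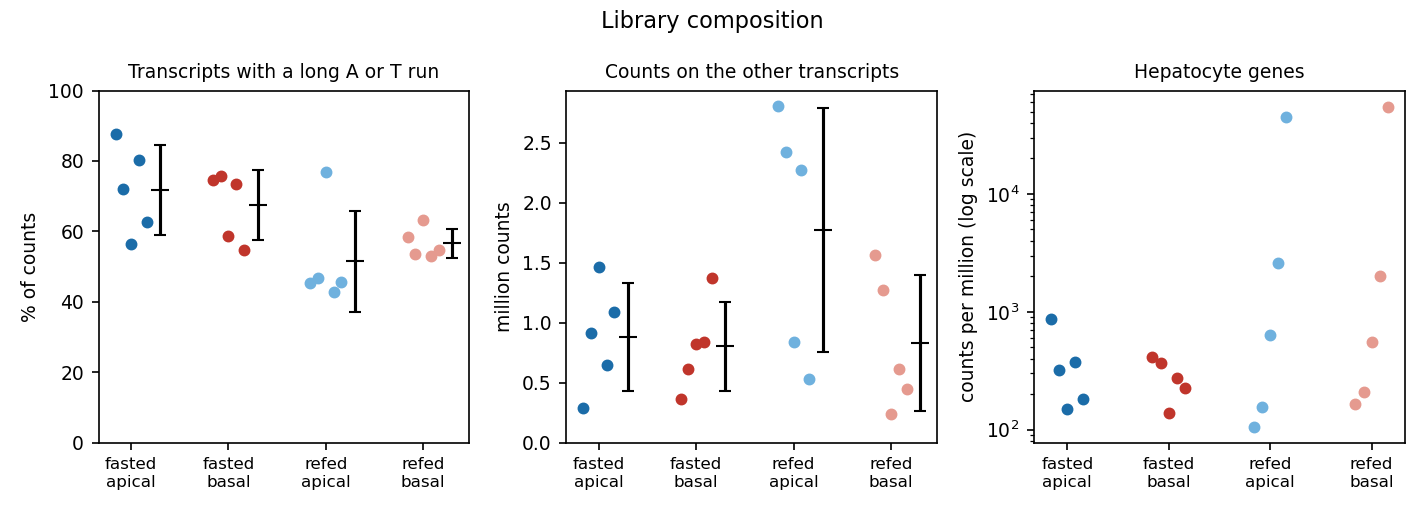
Share of counts on transcripts with a long A or T run (% of counts), counts on the other transcripts and hepatocyte genes (CPM of the counts left, log axis) in each library, with group mean ± SD (n = 5) in the first 2 panels. Refed apical library 3 stands at 76.9%, against 42.8 to 46.8% in the other 4 libraries of its group.

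Apical and basal fragments of fasted mice were compared to ask which mRNAs lie nearer the lumen and which nearer the base of the epithelium. Apob (12, 7977648 to 8016835) was higher in apical fragments by a log2 fold change of 2.88 ± 0.44 (SE; adjusted p = 5.98e-04), at 246 ± 80.6 against 33.0 ± 13.6 CPM (SD, n = 5). Mttp (3, 138089854 to 138144968), which loads lipid onto the Apob protein, was higher by 2.39 ± 0.35 (adjusted p = 5.12e-04; 894 ± 223 against 170 ± 50.9 CPM). Lct (1, 128284756 to 128328318), the lactase gene, was higher by 2.75 ± 0.48 (adjusted p = 0.00197; 375 ± 178 against 55.6 ± 29.7 CPM). Immunoglobulin and T-cell transcripts led the basal side, with Igha (12, 113254830 to 113260236) at 3.20 CPM in apical and 3115 CPM in basal fragments (log2 −10.36 ± 1.12).

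In all, 194 of 9742 genes passed the threshold in edgeR, 102 higher in apical and 92 higher in basal fragments. More of the calls were basal with DESeq2 size factors (87 apical, 105 basal), DESeq2 (177, 296), limma voom (267, 441) and no filter (110, 162), so which side has more called genes depends on the method. The other leading apical genes were Dag1 (2.63 ± 0.49), Abcc3 (2.38 ± 0.56), Abcb1a (2.37 ± 0.39), Malrd1 (2.28 ± 0.47), Enpep (2.26 ± 0.38), Clca4b (2.24 ± 0.37) and Heph (2.23 ± 0.41). The call of Dag1 ended with a gene length offset (1.53), and those of Abcc3, Apoe, H2-Q7, Pigr, Cdhr2, Dsc2, Epcam, P4hb, Slc15a1 and Slc2a2 without some single fasted libraries. The other leading basal genes were Igkc (−9.49 ± 1.18), Jchain (5, 88519809 to 88527891; −8.14 ± 0.87, 2.37 against 648 CPM), Apoe (−6.76 ± 1.55), Gzma (−4.86 ± 0.94), Ccl5 (−4.45 ± 0.86), Srgn (−3.20 ± 0.60), Net1 (13, 3882018 to 3918220; −2.87 ± 0.48, 14.2 ± 8.2 against 106 ± 51.5 CPM), Apobec3 (−2.86 ± 0.48) and H2-Q7 (−2.76 ± 0.67). For each of these genes all 5 apical libraries lay beyond the mean of the basal ones. Pigr (1, 130826684 to 130852249), the epithelial receptor for polymeric immunoglobulin, was also higher in basal fragments (−1.60 ± 0.37, adjusted p = 0.0158; 800 ± 240 against 2430 ± 836 CPM). Apoa4 (1.42 ± 0.43, adjusted p = 0.0840), Vil1 (0.52, 0.566), Rpl4 (−0.49, 0.731), Rplp0 (−0.20, 0.898), Eef1a1 (−0.27, 0.830) and mt-Co1 (0.19, 0.898) did not pass. On log2(TPM + 1) of the deposited TPM, which the long-run transcripts dominate, 1 gene was called apical and 111 basal, and after rescaling without those transcripts 56.1% of 164 calls were apical.

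By gene list, brush-border hydrolases were apical in fasted mice, with 17 of 18 genes positive and a median log2 fold change of 1.73. Of them 14 passed over all genes, among them Lct and Enpep, and 14 when adjusted over the list alone (camera adjusted p = 2.96e-18, and 0.00687 with an estimated correlation, given in this order for the other lists too). Transporters of both membranes were apical too. Of 27 apical-membrane transporters 26 were positive, with a median of 1.07, and 6 passed, among them Npc1l1 (2.03) and Slc15a1, or 16 adjusted over the list alone (3.53e-12; 0.00764). Of 19 basolateral-membrane transporters 17 were positive, with a median of 1.52, and 7 passed, among them Slc2a2 (1.52), or 11 adjusted over the list alone (3.24e-12; 0.0102). Of 21 genes of lateral and basal adhesion 18 were positive, with a median of 0.76, and 4 passed, among them Cdh1 (2.14), Dsc2 (1.93) and Epcam (1.22, adjusted p = 0.0475). Adjusted over the list alone 11 were higher and 1 lower (2.53e-07; 0.0460). Lipid uptake and chylomicron genes had 26 of 26 positive, a median of 0.94 and 6 past the threshold, including P4hb (1.52), or 16 adjusted over the list alone (1.68e-14; adjusted p = 0.0958 with an estimated correlation). Brush-border structure genes had 18 of 19 positive and a median of 0.43 (difference in level 0.47, and 0.27 without fasted basal library 1 or 0.29 without fasted apical library 5), with Cdhr2 (1.59, adjusted p = 0.0213) past the threshold and 2 adjusted over the list alone (6.14e-04; adjusted p = 0.478 with an estimated correlation). Leukocyte markers were basal, with 15 of 18 past the threshold and 17 adjusted over the list alone (8.82e-29; 2.26e-04). Of 12 stromal markers 6 passed and 10 adjusted over the list alone (7.70e-12; 0.00687), with Col3a1 at 6.22 CPM in basal and 0.0478 CPM in apical fragments. Endothelial markers were basal too, with 2 of 5 past the threshold (4.02e-04; 0.0392). Since basal fragments held RNA of these other cell types, epithelial RNA may make up a smaller share of them. Whether that raised the apical fold changes of epithelial genes, in either feeding state, was not tested.

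**Figure D2:**
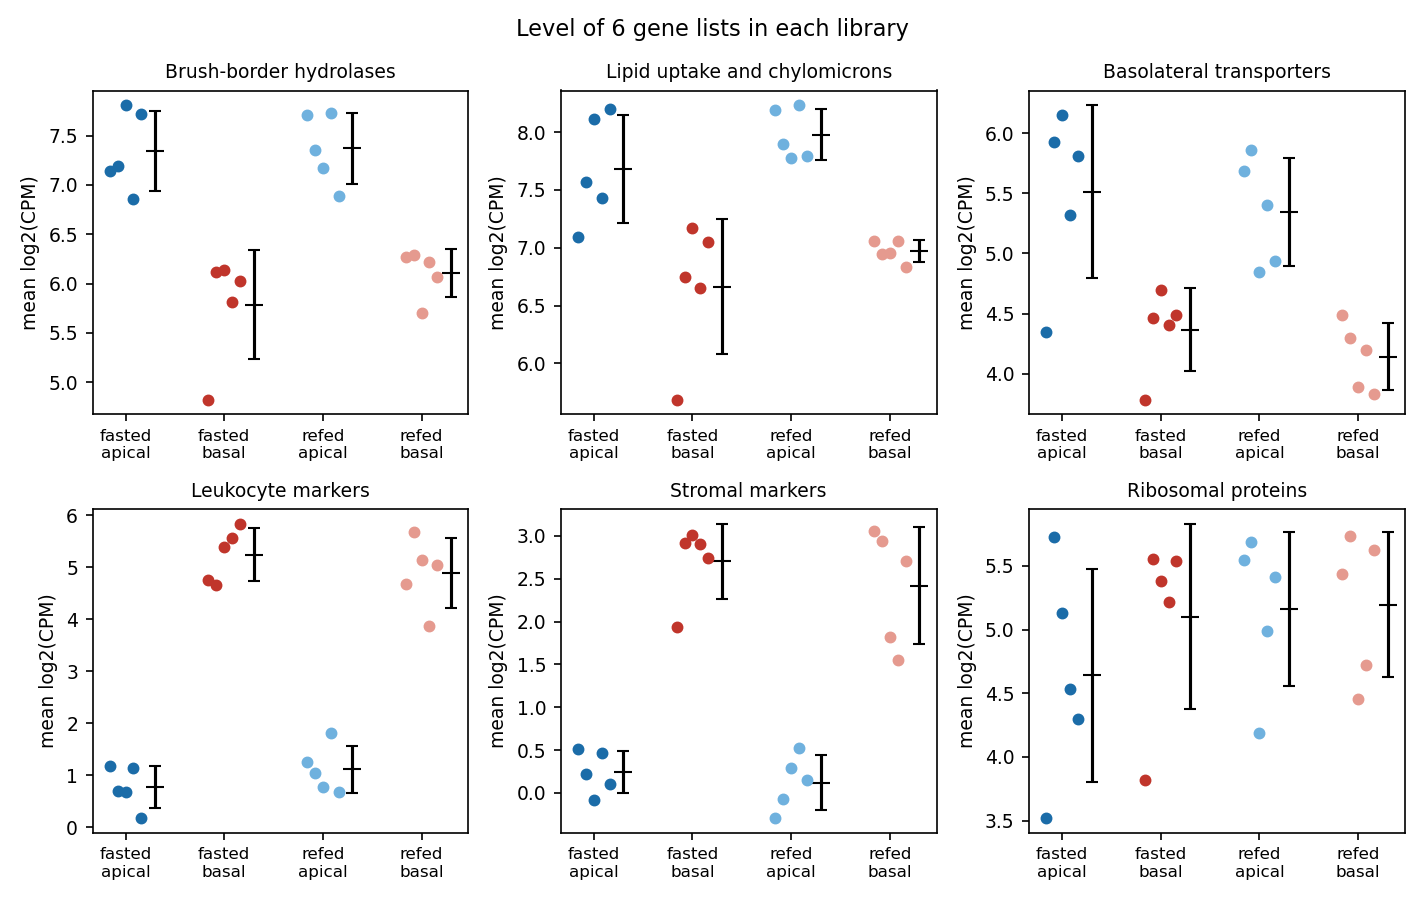
Mean log2 CPM of 6 gene lists in each of the 20 libraries, with group mean ± SD (n = 5). Brush-border hydrolases stood at 7.35 ± 0.41 in fasted apical and 5.78 ± 0.55 in fasted basal libraries, and leukocyte markers at 0.77 ± 0.41 and 5.24 ± 0.51.

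In refed mice Mttp, Apob and Lct were again among the leading apical genes, with Mttp higher in apical fragments by 2.42 ± 0.35 (adjusted p = 5.15e-04; 931 ± 168 against 174 ± 54.7 CPM), Apob by 2.52 ± 0.43 (adjusted p = 0.00196; 318 ± 121 against 55.2 ± 29.3 CPM) and Lct by 2.56 ± 0.47 (adjusted p = 0.00336). Dmbt1, a gene of mucosal defence, had the largest apical fold change (3.70 ± 0.84, adjusted p = 0.0163), and its call was lost without refed apical library 2 (2.53) or refed basal library 3 (3.63). Cyb5r3 (15, 83153494 to 83172592) was higher in basal fragments (−2.54 ± 0.37, adjusted p = 5.15e-04; 37.0 ± 10.2 against 215 ± 98.0 CPM), as were Net1 (−2.66 ± 0.48) and Pigr (−1.77 ± 0.37, adjusted p = 0.00873; 685 ± 190 against 2335 ± 698 CPM).

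In all, 306 genes passed, 126 higher in apical and 180 higher in basal fragments. Other leading apical genes were Malrd1 (2.75 ± 0.48), Heph (2.54 ± 0.42), Vnn1 (2.51 ± 0.61), Map7 (2.36 ± 0.64), Gpr155 (2.29 ± 0.56) and Dpp4 (2.27 ± 0.39). The other leading basal genes were Jchain (−8.06 ± 0.85), Igha (−6.56 ± 0.92), Igkc (−5.97 ± 1.00), Gzma (−3.91 ± 0.88), Ccl5 (−3.59 ± 0.79), Glrb (−2.87 ± 0.71), Apobec3 (−2.49 ± 0.47) and Tnfrsf10b (−2.28 ± 0.52). The calls of Vnn1, Map7, Gpr155, Glrb, Tnfrsf10b, Slc15a1 and Dsc2 ended without some single refed libraries, and that of Map7 also without single fasted libraries, with DESeq2 size factors (2.23), with at least 10 CPM (2.19) and with only the 10 libraries compared (2.34). Apoa4 (1.15 ± 0.42, adjusted p = 0.145), Vil1 (0.55, 0.464), Rpl4 (0.51, 0.672), Rplp0 (−0.32, 0.789), Eef1a1 (0.39, 0.698) and mt-Co1 (−0.10, 0.950) did not pass. With DESeq2 size factors 30.5% of the calls were apical, against 41.2% here, and on log2(TPM + 1) 17.1% were. After rescaling TPM without long-run transcripts 59.4% of 155 calls were apical, so which side has more called genes depends on the method.

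Brush-border hydrolases were apical in refed mice as well, with 17 of 18 positive, a median of 1.58, 11 past the threshold and 13 higher and 1 lower adjusted over the list alone (2.25e-11; 0.0405). Of the apical-membrane transporters 24 of 27 were positive (median 0.89), 5 passed and 12 adjusted over the list alone (3.53e-07; 0.0446). Of the basolateral-membrane transporters 18 of 19 were positive (median 1.34), 7 passed and 11 adjusted over the list alone (3.49e-08; 0.0446). Lipid uptake and chylomicron genes had 26 of 26 positive (median 0.84), with 8 past the threshold and 13 adjusted over the list alone (1.42e-11; adjusted p = 0.165 with an estimated correlation). Adhesion genes had 17 of 21 positive (median 0.72), with Dsc2 (2.02) and Cdh1 (1.66) past the threshold as higher and Cd44 (−3.73 ± 1.00, adjusted p = 0.0406) as lower. Adjusted over the list alone 9 were higher and 1 lower (9.41e-05; adjusted p = 0.161 with an estimated correlation). Brush-border structure genes had a median of 0.57, with 17 of 19 positive, 2 past the threshold, Cdhr2 at 2.13 (adjusted p = 0.00280), and 4 adjusted over the list alone (1.39e-04; adjusted p = 0.489 with an estimated correlation). Goblet-cell markers leaned basal, with 3 of 12 positive, a median of −0.98, 0 past the threshold and 0 adjusted over the list alone (difference in level −1.13, and −0.47 without refed apical library 5; 0.00315; adjusted p = 0.489 with an estimated correlation). Muc2 fell short (−1.63 ± 0.58, adjusted p = 0.130), as did Zg16 (−1.34, adjusted p = 0.215). Leukocyte markers had 10 of 18 past the threshold and 17 adjusted over the list alone (9.35e-20; 0.00201), stromal markers 8 of 12 and 10 (1.24e-11; 0.00803), and endothelial markers 2 of 5 and 3 (5.01e-04; 0.0446).

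Both feeding states shared most of their apical genes, among them Apob, Mttp, Lct, Malrd1 and Heph, and basal genes such as Igha, Jchain, Gzma, Net1, Apobec3 and Pigr. Of the apical calls 68 were shared (1.32 expected from independent lists, Fisher's exact p = 8.10e-112) and of the basal calls 56 (1.70 expected, p = 2.01e-76), and 0 genes were called on opposite sides. These p-values count genes as independent units although genes vary together, so they do not measure replication between mice. Of the 194 fasted calls 194 had the same sign in refed mice, and of the 306 refed calls 302 in fasted mice. Across all genes, which are not independent replicates, the fold changes of the 2 states had a Pearson r of 0.589 (Spearman 0.537), and 0.768 (0.647) over the 2726 genes with at least 20 CPM. Averaged over both states 1023 genes passed, 450 apical and 573 basal. They included Mttp (2.41 ± 0.25, adjusted p = 6.39e-07), Apob (2.70 ± 0.31, adjusted p = 2.07e-06), Cyb5r3 (−2.37 ± 0.26, adjusted p = 1.11e-06), Pigr (−1.69 ± 0.26) and Apoa4 (1.29 ± 0.30, adjusted p = 0.00518; 1.25, and not past the threshold, on log2(TPM + 1)). Of the basolateral-membrane transporters 13 of 19 passed in this average (adjusted p = 0.0198 with an estimated correlation), and of the lipid uptake and chylomicron genes 17 of 26 (adjusted p = 0.0976 with an estimated correlation). With DESeq2 size factors 32.6% of the averaged calls were apical, against 44.0% here, and on log2(TPM + 1) 27.2% were. After rescaling TPM without long-run transcripts 56.2% of 899 were.

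**Figure D3:**
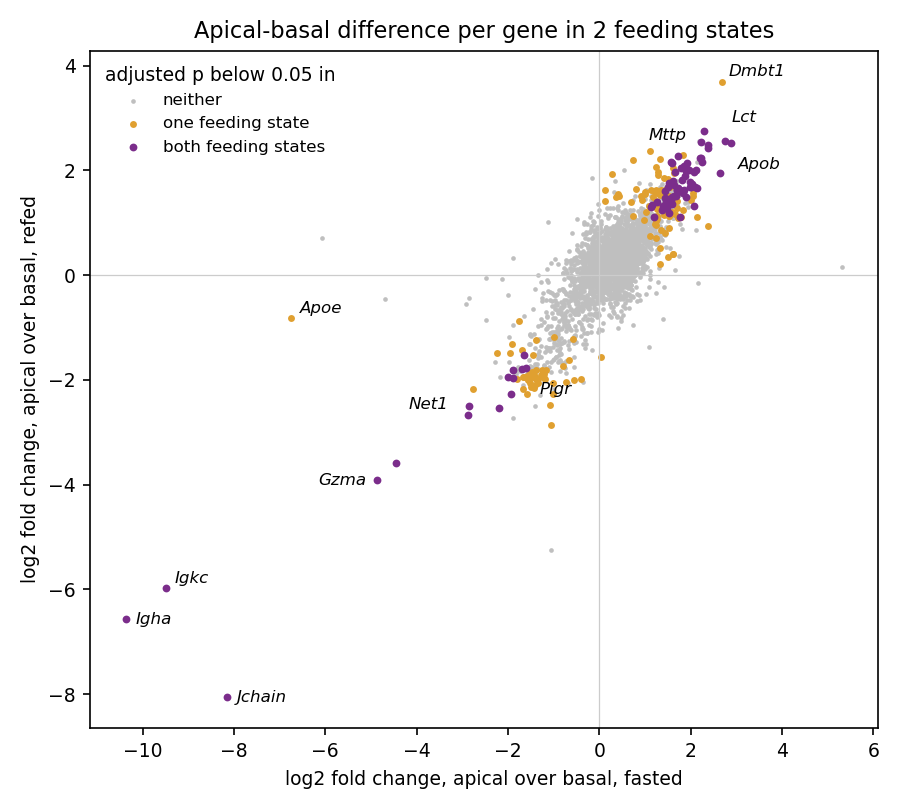
Log2 fold change of apical over basal fragments in fasted (horizontal axis) and refed mice (vertical axis) for each gene with at least 20 CPM, coloured by whether its adjusted p passed 0.05 in neither, in 1 or in both feeding states. Apob, Mttp and Lct lie at the upper right and Igha, Igkc and Jchain at the lower left.

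The difference between those 2 comparisons asks which mRNAs shift along the epithelium after a meal. In edgeR 0 genes passed, with 241 at an unadjusted p under 0.05 against 487 expected by chance, and DESeq2 and limma voom also called 0. Without a filter on low counts 18 were called, 12 with a positive and 6 with a negative change. The genes with the smallest p were Igha (3.80 ± 1.15), Apoe (5.93 ± 1.85, highest in the refed libraries 5 that also held hepatocyte genes), Igkc (3.52 ± 1.22), Atp6ap2 (1.45 ± 0.51) and Herpud1 (−1.29 ± 0.47), all with an adjusted p of 1. Of the gene lists only enteroendocrine hormones passed with the preset correlation, with a median of −1.33, 0 of 8 past the threshold and 2 positive (adjusted p = 0.0154, and 0.402 with an estimated correlation). Ghrl, Cck and Chga stand out in single libraries, Ghrl with 392 CPM in fasted basal library 3 and Cck with 326 CPM in fasted basal library 4 and 381 CPM in refed basal library 5. In simulated counts an 8-fold change of polarity was recovered for 78.8% of changed genes and a 4-fold one for 23.9%, so smaller shifts were mostly not detectable. The changed genes all had at least 20 CPM, and less abundant genes were not simulated as changed.

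Refed and fasted apical fragments were compared to ask what 2 h of feeding changes near the lumen. Dnase1 (16, 4036942 to 4040024) was higher in refed apical fragments (log2 2.39 ± 0.45, adjusted p = 0.0215; 161 ± 52.2 against 30.2 ± 22.9 CPM), with all 5 refed above all 5 fasted libraries. Tmem86a (7, 47050601 to 47054777) was higher too (2.58 ± 0.52, adjusted p = 0.0357; 38.9 ± 21.7 against 6.41 ± 1.32 CPM). The sulfate transporter gene Slc26a2 (18, 61192919 to 61211612) was lower (−1.54 ± 0.31, adjusted p = 0.0357; 56.4 ± 5.8 against 165 ± 35.7 CPM). Each of these 3 calls ended without some single libraries, with Dnase1 at 2.12 without fasted apical library 4, Tmem86a at 2.34 without refed apical library 1 and Slc26a2 at −1.38 without fasted apical library 5.

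Of the 9 calls the other 6, all lower in refed fragments, lay on transcripts with a long A or T run, among them Prrc2c (−3.05 ± 0.58), Efr3a (−2.62 ± 0.48), Nanos1 (−2.61 ± 0.45), Slx1b (−2.50 ± 0.50) and Pgpep1 (−2.12 ± 0.38). In all, 688 genes had an unadjusted p under 0.05. The share of counts on the Dock10 transcript was also lower after feeding, at 24.3 ± 5.2% against 45.6 ± 7.6% (exact permutation p = 0.00794, the smallest possible with n = 5, adjusted p = 0.0494). Feeding state thus coincided with a difference in library composition, and a batch between the 2 states cannot be told apart from feeding. Ribosomal protein genes leaned higher after feeding, with a median of 0.34 and 72 of 82 positive, 0 past the threshold and 0 adjusted over the list alone (3.97e-04; adjusted p = 0.742 with an estimated correlation). Their difference in level was 0.52, but −0.0105 over genes with at least 100 CPM, and fasted apical library 1 was the lowest of its group (3.52). The 13 genes of the mitochondrial genome, with mt-Nd2 at 0.63, were all positive with a median of 0.40 (0.00241; adjusted p = 0.742 with an estimated correlation). Brunner gland markers leaned lower, with Pdx1 at −1.76 (not past the threshold) and a median of −2.14 over 4 genes, 0 past the threshold and 1 adjusted over the list alone (0.00241; adjusted p = 0.0745 with an estimated correlation). Villus-tip genes leaned lower with a median of −0.46 and 1 of 13 positive (difference in level −0.76, and −0.45 without fasted apical library 5; 0.0312; adjusted p = 0.742 with an estimated correlation). Among them Ada (−4.59 ± 1.02, adjusted p = 0.0675) and Slc28a2 (−4.50 ± 0.98, adjusted p = 0.0618) did not pass, with fasted apical library 5 far above the rest. Lipid uptake and chylomicron genes had a median of 0.25, with 0 past the threshold and Fabp1 at 1.15 (adjusted p = 0.347; difference in level 0.30, and 0.15 without fasted apical library 1; 0.00876; adjusted p = 0.742 with an estimated correlation).

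On the basal side Dnase1 was again higher in refed fragments (2.82 ± 0.46, adjusted p = 0.00726; 104 ± 31.1 against 14.7 ± 0.85 CPM), with all 5 refed above all 5 fasted libraries. Its call ended without fasted basal library 2, 4 or 5 or refed basal library 3 (2.73). The other of the 2 calls was Pgpep1 (−2.34 ± 0.38, adjusted p = 0.00726), on a transcript with a long run. Ncoa4 (−3.38 ± 0.65, adjusted p = 0.0571), Sult6b2 (−2.79 ± 0.55, adjusted p = 0.0576) and Nanos1 (−2.22 ± 0.45, adjusted p = 0.0592; long run) did not pass. An unadjusted p under 0.05 was found for 643 genes. The 13 genes of the mitochondrial genome were all positive, with a median of 0.56 (difference in level 0.47, and 0.20 without fasted basal library 1 or 0.31 without refed basal library 5; 4.14e-06; adjusted p = 0.649 with an estimated correlation). Endoplasmic reticulum chaperones leaned higher with a median of 0.41 and 18 of 20 positive, Hspa5 at 0.77 and Edem1 at 1.15, 0 past the threshold (difference in level 0.53, and 0.28 without fasted basal library 1; 0.00118; adjusted p = 0.649 with an estimated correlation). Lipid uptake and chylomicron genes had a median of 0.23 (difference in level 0.31, and 0.06 without fasted basal library 1; 0.00580; adjusted p = 0.747 with an estimated correlation). In that list Apoc3 did not pass (1.67 ± 0.42, adjusted p = 0.174; 319 ± 177 against 99.9 ± 44 CPM) and had its highest value in refed basal library 5, where hepatocyte genes were also found. The Dock10 share was 25.9 ± 1.0% against 42.8 ± 6.1% (exact permutation p = 0.00794, adjusted p = 0.0494).

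Ribosomal protein mRNAs were compared as a list because the series title names translation. Their mean level was 4.64 ± 0.84 log2 CPM in fasted apical, 5.10 ± 0.73 in fasted basal, 5.16 ± 0.61 in refed apical and 5.19 ± 0.57 in refed basal libraries (SD, n = 5). The apical minus basal difference was −0.46 in fasted mice (exact two-sided permutation p = 0.373; −0.0067 over genes with at least 100 CPM) and −0.03 in refed mice (exact p = 0.929; 0.31 on log2(TPM + 1)). Its change on refeeding was 0.43 (exact p = 0.496; 0.13 over genes with at least 100 CPM). Refed minus fasted it was 0.52 in apical (exact p = 0.302) and 0.09 in basal fragments (exact p = 0.825). Over genes with at least 100 CPM both signs turned, to −0.0105 in apical and −0.14 in basal fragments. Over all 82 genes in fasted mice the median was −0.39 with 14 positive, and 0 passed over all genes or adjusted over the list alone (9.31e-04; adjusted p = 0.657 with an estimated correlation). In the average of both states Rps15a (−1.43, adjusted p = 0.0146), Rpl14 (−1.21, adjusted p = 0.0171) and Rpl30 (−0.89, adjusted p = 0.0326) were basal, though each of the 3 calls ended on log2(TPM + 1), as deposited and rescaled. Those of Rps15a (−1.26) and Rpl30 (−0.84) also ended with a gene length offset, and that of Rpl30 without a filter (−0.79), without the 3 low libraries (−0.78), without refed libraries 5 (−0.88) and without some single libraries. None of these differences in level exceeded the spread between libraries.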

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

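Of the tests here, the stromal test of basal genes, the over-representation of genes on long-run transcripts, the estimated correlation for ribosomal proteins, the version of the basal-gene test with at least 20 CPM and the test of the counts left between the sides were chosen after the result was seen.

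Genes higher in basal fragments outside the marker lists could come from lamina propria cells captured with the basal areas. Over 500 such genes the median within-state correlation with the leukocyte marker level across 10 basal libraries was −0.143, against 0.0875 for 10000 random lists matched on expression (95% of them between 0.0476 and 0.124), a percentile of 0. Over the 150 genes with at least 20 CPM it was −0.311 against 0.192, again at percentile 0, while the leukocyte markers themselves had a median r of 0.593; without fasted basal library 1 the 500 genes stood at −0.0608 (other genes −0.0141) and the 150 at −0.149 (other genes 0.0287). The high correlation that leukocyte RNA predicted was thus not seen for the set as a whole. That does not decide the question, since the 0.593 counts each marker within its own level. The gap to other genes also narrowed without fasted basal library 1, so leukocyte RNA stays open. The r of Pigr was 0.356 with the leukocyte and 0.479 with the stromal level, of Cyb5r3 0.424 and 0.726 and of Net1 0.634 and 0.585, not tested for single genes. RNA of stromal cells stays open: the 500 genes stood at −0.125 against the stromal marker level (random lists 0.201, percentile 0; 0.0018 without fasted basal library 1 and −0.312 without refed basal library 4), but the 12 stromal markers followed the rest of their own list with a median r of only 0.180, from −0.0641 without refed basal library 4 to 0.286 without refed basal library 3, so that test decides nothing, and endothelial RNA or a position on the basal side of epithelial cells was not tested.

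Of the 9 genes called between refed and fasted apical fragments, 6 lay on transcripts with a long A or T run, against 0.642 expected (Fisher's exact p = 9.00e-06), which is consistent with reads of poly(A) sequence assigned to them. Dnase1, Slc26a2 and Tmem86a have 0% of their counts on such transcripts, which argues against that source for these 3, and leaving the transcripts out tested only the scaling, with a largest move of a fold change towards 0 of 0.0048. Their adjusted p became 0.0588, 0.0588 and 0.0685, because fewer small p-values remained in the adjustment and not because the folds changed. Feeding and an unrecorded library batch cannot be told apart, since every refed library had a lower Dock10 share (18.4 to 32.5%) than every fasted one (34.1 to 55.6%).

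The ribosomal protein list was lower in fasted apical than basal fragments by the preset correlation. With the correlation between its genes estimated from the libraries the adjusted p was 0.657, consistent with genes that vary together between libraries of a group. Within groups the level followed the counts left per library (Pearson r = 0.616, permutation p = 0.00727, Spearman 0.577, p = 0.0149, and r = 0.687 without the 2 farthest of 20 libraries). An effect of depth between libraries predicted such an r, but the counts left also fall with the share on long-run transcripts. Depth and library composition were thus not told apart. A difference in the counts left between the sides is argued against as the cause. The difference in level was −0.49 after removing the slope on the counts left and −0.46 before (exact p = 0.198 and 0.373). Whether these mRNAs differ between the sides beyond that spread stays open.

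Grouping by chance was tested by refitting other splits of the same libraries, 100 per comparison with the real one included. These splits treat libraries as independent, which the labels do not establish. On that condition chance can be excluded for apical against basal fragments in fasted mice (194 genes, as many in 1 split, highest other 3), in refed mice (306, 1 split, highest other 19) and in both (1023, 1 split, highest other 11). For refed against fasted basal fragments 2 of the 100 splits, the real one included, gave as many as the real 2 genes. A rule set beforehand on the share of splits would have excluded chance here. It was set aside, since the highest other count was also 2. Another split thus equalled the real count, and chance is not excluded. Chance cannot be excluded either for refed against fasted apical fragments (9 genes, 5 splits, highest other 622). The split with 622 genes points to a structure of the samples, which was not identified. For the change of polarity the real count is 0, so all 100 splits reach it by construction and say nothing about chance (highest other 14).

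A single library stood far from the other 4 of its group in 55 of 460 sets of values tested. For independent, normally distributed values about 1 in 20, or 23, would be flagged. Since 37 of the 55 were unlogged CPM values of single genes, which need not be normal, 23 is no firm chance level. Of the 55 flags, 13 were in fasted basal library 1, which has few counts outside long-run transcripts, and 6 each in fasted apical library 1, refed apical library 5 and refed basal library 5.

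Among library measures, refed apical library 3 had 76.9% of its counts on long-run transcripts, against 42.8 to 46.8% in the others. Counts on transcripts matched to no gene, which no gene comparison used, reached 0.686% in refed apical library 5, the highest share of any library, and 0.551% in refed basal library 5. That share was higher after feeding on both sides, at 0.406 ± 0.157% against 0.239 ± 0.018% in apical and 0.398 ± 0.088% against 0.265 ± 0.022% in basal libraries (exact permutation p = 0.00794, adjusted p = 0.0494, on each side).

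Fasted basal library 1 had the lowest levels of its group (mean log2 CPM) for ribosomal proteins (3.82), translation factors (4.36), the mitochondrial genome (8.79), brush-border hydrolases (4.82), adhesion (3.92), cholesterol synthesis (2.24), endoplasmic reticulum chaperones (3.80), antimicrobial genes (4.82) and stroma (1.94). It was also lowest for Apob (9.6 CPM), Mttp (80.01 CPM) and Clca4b (34.1 CPM), and stood apart for Glrb (128 CPM). Fasted apical library 1 stood apart for endoplasmic reticulum chaperones (4.76), antimicrobial genes (5.55), Igha (10.9 CPM), H2-Q7 (23.1 CPM), Glrb (93.9 CPM) and Apoe (4.08 CPM). Fasted apical library 2 did so for Rpl14 (31.0 CPM), and fasted apical library 5 for Ada (1135 CPM) and Slc28a2 (134 CPM). Fasted basal library 2 stood apart for Apobec3 (305 CPM), library 3 for Ghrl (392 CPM) and Chga (7.83 CPM), library 4 for Cck (326 CPM) and Ocln (1.78 CPM), and library 5 for endothelium (4.43).

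Refed apical library 1 stood apart for Hspa5 (312 CPM), library 2 for Dmbt1 (529 CPM), Sult6b2 (598 CPM) and Pdx1 (37.1 CPM), library 3 for Slx1b (996 CPM) and Ghrl (12.1 CPM), and library 4 for Jchain (5.98 CPM) and Cck (8.89 CPM). Refed apical library 5 did so for fatty acid synthesis (3.94), Igkc (230 CPM), Apoe (476 CPM), Slc26a2 (46.2 CPM) and Edem1 (8.57 CPM). Refed basal library 2 stood apart for Net1 (163 CPM) and Cyb5r3 (383 CPM), and library 3 for amino acid stress genes (1.51), goblet markers (4.19), Tnfrsf10b (102 CPM) and Rpl14 (14.8 CPM). Refed basal library 5 did so for Apoe (658 CPM), mt-Co1 (1542 CPM), Ghrl (8.77 CPM), Cck (381 CPM) and Apoc3 (627 CPM).

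The polarity of enteroendocrine hormone genes differed between feeding states by the interaction test (adjusted p = 0.0154, 0.402 with an estimated correlation), and rests on single libraries for Ghrl and Cck.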

How the results depend on the processing

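All versions without certain transcripts, without named sets of libraries or marker genes, and with rescaled TPM were chosen after the data were seen, and the other alternatives were planned.

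For the named genes of all comparisons, alternatives chosen beforehand gave 6890 values on the same side of the threshold, 271 newly past it, 180 no longer past it and 0 reversed. Single libraries left out gave 17367, 84, 409 and 0, and alternatives added later 7380, 72, 119 and 7. Below, counts are given in the order fasted polarity (194), refed polarity (306), change of polarity (0), refed against fasted apical (9), basal (2) and polarity in both states (1023), where they moved by over 1.5 times, and the cause was not tested unless stated.

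DESeq2 called 473 fasted, 737 refed, 87 apical feeding, 47 basal feeding and 1540 joint polarity genes, and limma voom 708, 1099, 153, 14 and 2135. Both called 0 for the change of polarity. Without a filter 462 refed polarity, 18 change, 245 apical and 190 basal feeding genes were called, with 161 of the apical and 138 of the basal feeding genes higher after feeding, against 2 of 9 and 1 of 2. With at least 10 CPM 14 apical feeding genes were called. With DESeq2 size factors in edgeR 4 basal feeding genes were called, 1 of them higher after feeding against 1 of 2, and the median of all genes moved from −0.01 to −0.13 (fasted polarity), 0.03 to −0.12 (refed) and 0.02 to −0.11 (both). On log2(TPM + 1) the counts were 112, 82, 3 and 8 for the single comparisons and 434 for joint polarity, with the median of all genes at 0.38 for refed polarity, 0.43 for the change, 0.50 for apical feeding and 0.16 for both, and with 0.0% of apical and 12.5% of basal feeding genes higher after feeding, against 22.2% and 1 of 2. Rescaling TPM without long-run transcripts gave 155 refed polarity (59.4% apical), 5 apical (60.0% higher after feeding) and 0 basal feeding genes, and 56.2% apical in joint polarity. With only the 10 libraries compared, 92 fasted polarity, 0 apical and 19 basal feeding genes were called.

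Without long-run transcripts 0 apical feeding genes were called, since 6 of the 9 are removed and the rest ended near the threshold, and without A/T-rich ones 2. Without the 3 libraries under 400000 counts it was 0 apical and 1 basal feeding gene, and with both changes 0 and 0. Without refed libraries 5 of both sides it was 130 refed polarity and 0 apical feeding genes. Without refed apical library 3 and long-run transcripts it was 51 apical and 4 basal feeding genes, and without it and A/T-rich transcripts 6 and 5. Leaving out marker genes of other cell types or using a length offset moved no count by over 1.5 times.

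The replicate number used as a block raised calls to 529 fasted, 677 refed, 26 apical and 18 basal feeding genes, moved the lists past the threshold to 5 for the change of polarity and 9 for basal feeding, and gave ribosomal protein p-values of 0.125, 0.813 and 0.127 for fasted, refed and change. The labels do not pair the numbers, so they were not taken as pairs. Deviations of same-number libraries were all positively correlated, though weakly in some pairs (r from 0.033 to 0.303 in fasted and 0.045 to 0.205 in refed mice). As a hint of a shared source, every refed apical library matched its own number best. Fasted 1 and 5 did, but 2, 3 and 4 did not. Hepatocyte genes were high in both libraries of refed numbers 4 and 5. If numbers pair the sides, the main polarity counts ignore this and the block fits polarity, not feeding, as no mouse had both states.

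Leaving out each library in turn gave 74 to 309 genes for fasted polarity, 99 to 427 for refed, 0 to 0 for the change, 0 to 261 for apical feeding, 0 to 11 for basal feeding and 787 to 1351 for both. Fasted polarity moved over 1.5 times without fasted apical library 1 (309), 2 (125), 3 (74) or 5 (78) or fasted basal library 2 (117). Refed polarity did so without refed apical library 1 (99), 2 (102) or 4 (134) or refed basal library 1 (184), 3 (127) or 5 (167). Apical feeding gave 0 without fasted apical library 1 or 4 or refed apical library 4 or 5, 19 without refed apical library 2 and 261 without library 3, whose share of long-run transcripts stands apart. Basal feeding gave 0 without refed basal library 3, 1 without fasted basal library 2, 4 or 5, and 4 to 11 without fasted apical library 1 (8), fasted basal library 1 (5), refed apical library 2 (11), 3 (11) or 4 (4) or refed basal library 2 (9).

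Gene lists past the threshold (15, 13, 1, 9, 5 and 17) fell to 7, 6, 0, 0, 0 and 6 with an estimated correlation, since it widens the null for genes that vary together. With fry 9 fasted, 0 change, 1 apical and 0 basal feeding lists passed. For the change of polarity 2 lists passed without A/T-rich transcripts and 3 without the 3 low libraries. Leaving out 1 library gave 11 to 19, 10 to 15, 0 to 4, 6 to 11, 4 to 11 and 15 to 18 lists.

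Over genes with at least 100 CPM the ribosomal protein difference fell from −0.46 to −0.0067 in fasted polarity and from 0.43 to 0.13 in the change, and on log2(TPM + 1) it rose from 0.52 to 1.08 in apical feeding and from 0.43 to 0.90 in the change. It reversed in refed polarity on log2(TPM + 1) (0.31) and over genes with at least 100 CPM (0.12), in apical feeding over those genes (−0.0105), and in basal feeding over those genes (−0.14) and without the 3 low libraries (−0.0319). Its ranges without 1 library were −0.79 to −0.15 (fasted), −0.21 to 0.22 (refed), 0.13 to 0.77 (change), 0.23 to 0.80 (apical feeding) and −0.23 to 0.28 (basal feeding). It changed sign in refed polarity without refed basal library 1 (0.04), 2 (0.11) or 5 (0.08) or refed apical library 3 (0.22) or 4 (0.02), and in basal feeding without fasted basal library 1 (−0.23) or refed basal library 2 (−0.04) or 5 (−0.01).

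The 7 reversals of named genes arose where long-run or A/T-rich transcripts were removed. Prrc2c in apical feeding was 1.47 without long-run transcripts and low libraries and 0.38 on rescaled TPM. Pecam1 in fasted polarity was −7.45, −7.44, −7.52 and −7.44 without long-run or A/T-rich transcripts, alone or with refed apical library 3 left out, against 0.75. Its counts then were 0 in every fasted apical library, so these fitted values depend on the default prior count of edgeR and are no bound. Per3 in joint polarity was −2.99 without long-run transcripts and low libraries.

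With 242141 to 2808070 counts per library outside long-run transcripts, a common biological coefficient of variation of 0.697 and 5 libraries per group, simulated 2-fold changes were recovered for 3.0% of genes in apical and 4.5% in basal feeding. Which of these sets that limit was not tested.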

Other observations

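The hepatocyte hypothesis came from genes whose values had been seen, and its test used only list genes that had not been seen. Gm10800 and Gm10801 were chosen for mention after their values were seen.

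Ada (2, 163726584 to 163750239) and Slc28a2 (2, 122426477 to 122461137), an adenosine deaminase gene and a nucleoside transporter gene, had lower means after feeding. With all libraries they did not pass the threshold on either side. Without refed apical library 3, Ada passed in the apical comparison (log2 −4.38 ± 1.10, adjusted p = 0.0281). That version called 261 genes, 159 of them on long-run transcripts. With long-run transcripts also left out, 51 genes were called. Ada was then no longer among the largest called decreases, which Usp14 led (−4.10) among genes with at least 20 CPM. Ada averaged 284 ± 477 CPM in fasted and 11.4 ± 9.1 CPM in refed apical libraries (SD, n = 5), and Slc28a2 36.3 ± 55.3 and 1.34 ± 2.0 CPM. Fasted apical library 5 held 1135 CPM of Ada and 134 CPM of Slc28a2, and without it the log2 change of Slc28a2 in edgeR was −2.87 (adjusted p = 0.394), against −4.50 with it. On the basal side Ada changed by −2.36 ± 0.94 (adjusted p = 0.640) and Slc28a2 by −2.67 ± 0.95 (adjusted p = 0.522).

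Hepatocyte transcripts stood out in refed libraries 5 and, less so, 4. Of the counts left outside long-run transcripts, a list of 33 hepatocyte genes had 45420 CPM in refed apical library 5, 55220 in refed basal library 5, 2571 in refed apical library 4 and 2019 in refed basal library 4, against 106 to 875 in the others. Alb had 4359, 4199, 1010 and 290 counts in those 4 libraries, and Ttr had 737 and 1005 in both libraries 5. The hypothesis is that hepatocyte RNA entered these libraries. It predicted that over 80% of the list genes not seen before would be higher in both refed libraries 5 than in every library other than refed 4 and 5, and 24 of 25 were (96.0%), which is consistent with it. The fragments were taken by laser from sections, with no sort or gate that removes such RNA, and 0 of the 33 genes are in another list used here, while 26 had at least 3 counts in some of the 16 other libraries. Without refed libraries 5 of both sides 130 genes were called for refed polarity against 306, and the cause of that drop was not tested.

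Transcripts of the predicted genes Gm10800 (2, 98666547 to 98667301) and Gm10801 (2, 98662237 to 98664083) took a larger share of basal than of apical libraries. Gm10800 took 0.755 ± 0.29% of fasted apical and 3.20 ± 1.25% of fasted basal counts, and 1.06 ± 0.44% and 3.92 ± 0.52% in refed mice (exact permutation p = 0.00794 with n = 5, adjusted p = 0.0494 over 56 tests, in both states). Gm10801 took 0.127% and 0.563%, and 0.188% and 0.720%, with the same p.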
